A study of Homo sapiens with 18 samples.

How the data were processed

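Single-cell RNA sequencing libraries of the 10x Chromium 5' kit, version 1, were made from fresh dissociated tissue, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger 5.0.0 per the file headers and made on the GRCh38 build per the submitters' processing notes. They list 36601 human genes and 0 viral genes, so HPV transcripts were not analysed here. The gene model release, the treatment of introns and the cell-calling settings are not given in the sources used here. Each library has its own matrix, with no deposited cell annotation. Counting at the 5' end makes counts depend little on transcript length. Gene positions are 1-based and come from GENCODE release 29 on GRCh38, matched by gene identifier (82 named genes found).

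The groups (14 tumors, 3 normal samples, 1 metastasis) come from the tissue labels, and each library counts as 1 replicate. No pair of libraries had identical counts. The labels tie normal replicates 1, 2 and 3 to the donors of tumors, so pairing comes from the donor itself and no check of correlation between paired libraries was run. The bracketed sample labels have a hyphen in all normal and 9 tumor libraries and an underline character in 5 tumors and the metastasis, which was treated as a candidate batch. The second style holds no normal library, so it gives no comparison of its own. Dates, kits and lanes are not given in the sources used here.

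Barcodes with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept (81039 of 88314). Doublets were scored with Scrublet in scanpy 1.11.5, and the 3511 highest-scoring barcodes were removed, at a rate of 0.8% per 1000 barcodes of a library. Counts were scaled per cell and log-transformed, 2000 variable genes gave 40 principal components, and a graph of 20 neighbors was clustered with the Leiden method (leidenalg 0.10.2, resolution 1.5) without integration of libraries. T or NK-like, B-like and myeloid-like cells were clustered again within the class. Immunoglobulin, T cell receptor, XIST and Y-linked, mitochondrial and ribosomal genes were left out of clustering, and XIST and Y-linked genes out of every test. A cluster took a name ending in -like from marker genes fixed before the data were examined, with at least 3 markers detected, and stayed unnamed where its leading genes went against the name. The rule for detecting a marker (at least 10% of the cells and a log2 fold of at least 1) was set with the data at hand. Names rebuilt in this way can differ from those of the study.

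Shares of cells were compared with two-sided exact permutation tests of the difference in means over every split of the libraries, with Benjamini-Hochberg adjustment over the 9 classes and, apart, over the 10 subsets. Subset shares used libraries with at least 50 cells of the parent class. For expression, UMI counts were summed per library and class where a library had at least 20 cells of it and a class had at least 2 normal and 6 tumor libraries. Mast-like, plasmacytoid dendritic-like, NK or innate lymphoid-like and dendritic-like cells did not reach this and were not tested. List counts are over the members measured in a class. The sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood fit, R 4.3.3), with adjusted p under 0.05 taken as past the threshold. CPM values are a gene's counts scaled to a common total per library and class (edgeR cpm). Gene lists fixed before the data were examined were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Main p-values of this single series treat libraries as independent, but 3 donors gave both tissues.

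Genes named in the text follow a rule fixed before the data were examined. They are up to 3 members per list and direction past the threshold, and the 8 largest changes each way among genes with a mean of at least 50 CPM and every normal library on the same side of the tumor median, at most 30 per class. The cap took the largest changes first, then list members by adjusted p, and markers that define a class are not named in it. The text prints 104 of these pairs of gene and class, and some that meet the rule are not reported here. HLA genes, KRT86, PAGE1 and MAGEA10 have alleles or near-identical relatives, so their counts are uncertain. The metastasis was set against its primary tumor by ratios of CPM in epithelial-like cells (at least 50 UMIs over both libraries), with a floor of 3 UMIs where a library had 0, and list medians were ranked among 10000 random lists matched on expression. Relations across tumors used mean log2 CPM with a prior of 1.

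The edgeR and camera fits, the share and relation tests and the metastasis intervals were tested on simulated data, and the random-list percentiles and sign-flip tests were not. With 200 genes changed among counts simulated from the T or NK-like libraries (11426 genes), edgeR found 28.4% of 2-fold and 84.5% of 4-fold changes, with 3 false among 112 calls. For epithelial-like cells (16370 genes) it found 1.05% and 24.7%, with 0 false among 23 calls. The share test called 4.86% of 10000 unchanged draws and 99.3% of those shifted by 3 SD. The metastasis intervals left out 0 for 100% of 4-fold changes and 5.66% of unchanged genes. The alternatives tried were other normalizations, filters and DESeq2 1.42.0, the donor as a block, each normal library left out, the tumors of the normal label style, the metastasis added, other cell filters, depths, doublet treatments and clusterings, and other scales and denominators of the shares. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.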

Results

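Tumor tissue from 14 donors with head and neck squamous cell carcinoma positive for human papillomavirus (HPV), a virus-driven cancer of the lining of the mouth and throat, was dissociated into single cells. The cells were profiled by droplet-based RNA sequencing at the 5' end of transcripts, in which unique molecular identifiers (UMIs) count RNA molecules. The 18 libraries held 14 primary tumors (1 per donor), 3 samples of adjacent normal tissue from the donors of tumor replicates 11, 12 and 13, and 1 metastasis from the donor of tumor replicate 10. The labels' protocol names tonsil as the kind of normal tissue. A library held 16588507 to 17442529 UMIs in normal tissue, 23807967 to 55840531 in tumors and 39290794 in the metastasis. Of 88314 barcodes, 77528 were kept as cells, 63897 from tumors, 10049 from normal tissue and 3582 from the metastasis. The median UMI count per cell ran from 3069 to 3732 in the normal libraries and from 1616 to 11938.5 in the tumors, and was 10047.5 in the metastasis. The series asks how cell composition and transcriptomes differ, so each comparison below sets the tumor libraries against the normal ones, with the library as the replicate.

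Clusters of cells were named from fixed marker genes, and the names are those of cells that look like a type. Epithelial-like cells fell into 20 clusters and T or NK-like cells into 11. The clusters that held most of a class differed between tissues. Among B-like cells cluster 3 held 38.8% of the tumor cells and cluster 12 39.3% of the normal cells (52.3% of cluster 12 came from 1 library). Among T or NK-like cells cluster 0, led by TIGIT and FOXP3, held 18.2% of the tumor cells, and cluster 5, led by CD3E and IL7R, 37.2% of the normal cells. Endothelial-like, mast-like and plasmacytoid dendritic-like cells of both tissues sat mainly in the same clusters. Unnamed cells made up 0.762% ± 2.78 of the cells in tumors and 0.00923% ± 0.0160 in normal tissue. Within a class, the unnamed share was 26.1% ± 8.70 and 15.3% ± 18.8 of T or NK-like cells, 5.56% ± 9.27 and 2.56% ± 1.93 of B-like cells, and 6.54% ± 3.12 and 17.8% ± 18.3 of myeloid-like cells (SD, n = 14 tumor and 3 normal libraries).

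Tumors held a larger share of epithelial-like cells and a smaller share of B-like cells than normal tissue. Epithelial-like cells, which carry keratins and line mucosal surfaces, made up 38.2% ± 19.4 (SD, n = 14) of the cells in tumors and 2.33% ± 0.556 (n = 3) in normal tissue. B-like cells made up 10.5% ± 8.42 (SD, n = 14) of the cells in tumors and 37.8% ± 12 (n = 3) in normal tissue. All 14 tumors lay above every normal library for epithelial-like cells and below every normal library for B-like cells. Both differences passed a two-sided exact permutation test over 680 splits of the libraries (p = 0.00147, the smallest it can give, adjusted p = 0.0066 over the 9 classes). Myeloid-like cells made up 5.71% ± 2.64 (SD, n = 14) of the cells in tumors and 1.63% ± 0.563 (n = 3) in normal tissue. All 14 tumors lay above the normal libraries, but the permutation test did not pass (adjusted p = 0.075, and adjusted p = 0.0066 on the logit scale). T or NK-like cells (34.0% ± 14.9 against 49.3% ± 12.7, adjusted p = 0.27), plasma-like cells (4.87% ± 2.71 against 3.51% ± 0.665, adjusted p = 0.63), fibroblast or mural-like cells (3.62% ± 3.71 against 3.31% ± 1.30, adjusted p = 0.98), endothelial-like cells (1.58% ± 0.749 against 1.65% ± 1.03, adjusted p = 0.97) and plasmacytoid dendritic-like cells (0.308% ± 0.261 against 0.211% ± 0.268, adjusted p = 0.75) differed by less than the exact test could separate. Mast-like cells (0.399% ± 0.264 against 0.190% ± 0.175, adjusted p = 0.37) fell into 2 clusters, of which number 49 (75 cells, all from 1 tumor, 28.4% of the tumor cells of the class) was led by TPSAB1, TPSB2 and CPA3 together with the epithelial genes KRT13, KRT6A and KRT16. Without it, mast-like cells made up 0.331% ± 0.210 against 0.190% ± 0.175 (permutation adjusted p = 0.53). Within the 3 donors with both tissues, the mean difference was -25.8 points for B-like and 48.1 points for epithelial-like cells, where an exact sign-flip test cannot go below p = 0.25. Against the 9 tumors whose labels share the style of the normal libraries, the differences were -27.0, 37.7 and 3.15 points for B-like, epithelial-like and myeloid-like cells. As a percentage of immune cells over all 14 tumors, T or NK-like cells turned from lower to higher in tumors (7.08 points, permutation adjusted p = 0.29). The differences for plasma-like, plasmacytoid dendritic-like, fibroblast or mural-like and endothelial-like cells, none of which passed, also changed direction under at least 1 alternative.

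**Figure D1:**
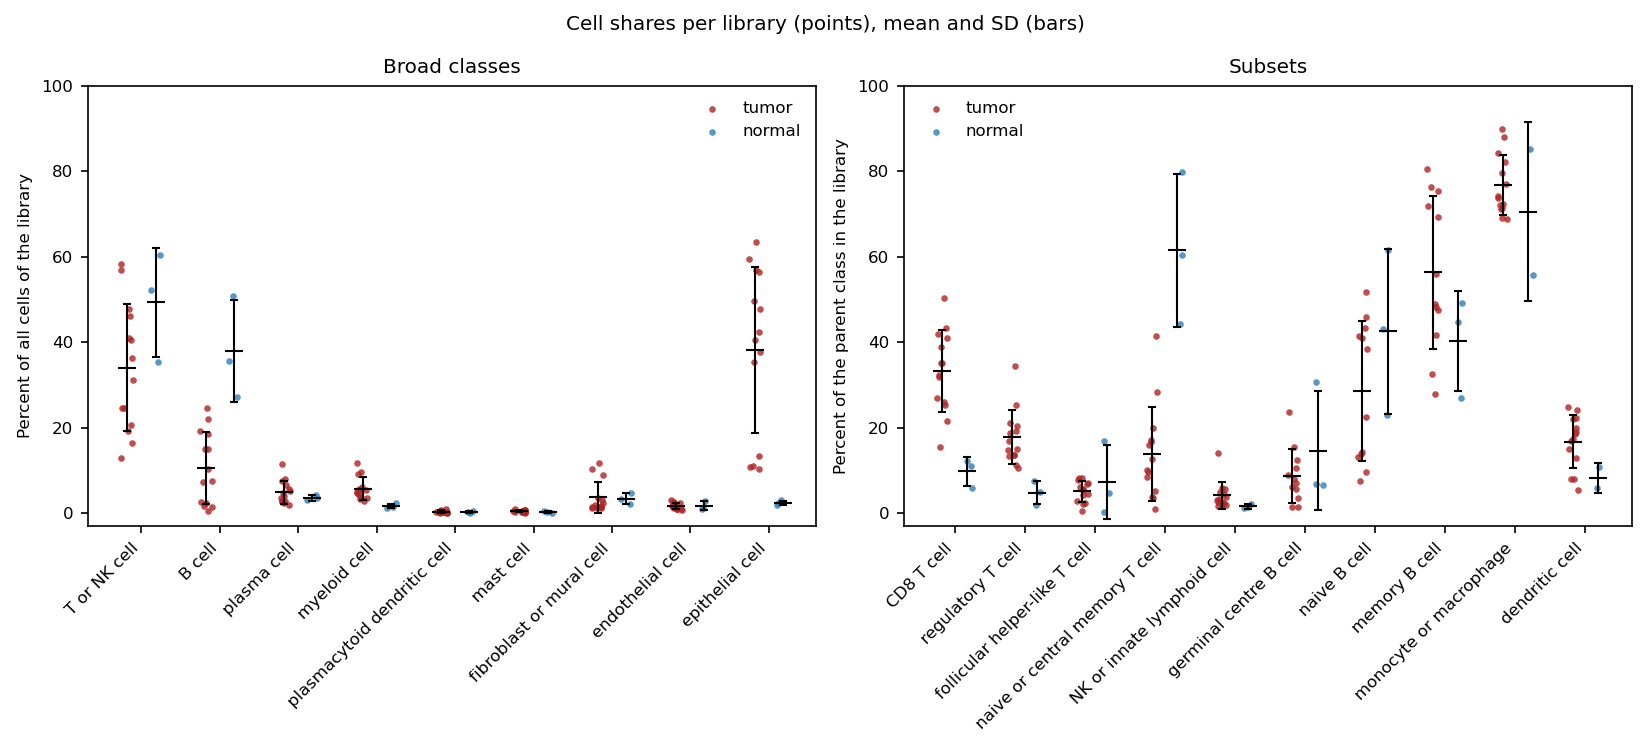
Percentage of cells per library (vertical axes) for each broad class, as a share of all cells, and for each subset, as a share of its parent class; points are libraries (14 tumors in red, 3 normal in blue) and black bars the mean ± SD. Epithelial-like cells averaged 38.2% in tumors and 2.33% in normal tissue, and naive or central memory T-like cells 13.8% and 61.5% of the T or NK-like class.

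Inside the T or NK-like class, the composition also differed. CD8 T-like cells, the cytotoxic lineage, made up 33.2% ± 9.52 (SD, n = 14) of them in tumors and 9.70% ± 3.35 (n = 3) in normal tissue (adjusted p = 0.0074 over the 10 subsets). Regulatory T-like cells, which restrain other T cells, made up 17.7% ± 6.35 (SD, n = 14) of them in tumors and 4.73% ± 2.74 (n = 3) in normal tissue (adjusted p = 0.025). Naive or central memory T-like cells, which recirculate through lymphoid tissue, made up 13.8% ± 10.9 (SD, n = 14) of them in tumors and 61.5% ± 17.9 (n = 3) in normal tissue (adjusted p = 0.0074). All 14 tumors lay above every normal library for CD8 and regulatory T-like cells and below for naive or central memory T-like cells. Follicular helper T-like cells (5.06% ± 2.45 against 7.21% ± 8.67, adjusted p = 0.36) and NK or innate lymphoid-like cells (4.13% ± 3.20 against 1.55% ± 0.590, adjusted p = 0.29) did not pass. Nor did germinal center B-like (8.65% ± 6.34 against 14.6% ± 13.9, adjusted p = 0.32), naive B-like (28.5% ± 16.5 against 42.5% ± 19.3, adjusted p = 0.30) or memory B-like cells (56.3% ± 18 against 40.3% ± 11.7, adjusted p = 0.29), as shares of B-like cells in 12 tumor and 3 normal libraries. With only 2 normal libraries of enough myeloid-like cells, monocyte or macrophage-like (76.7% ± 7.0 against 70.6% ± 20.9, adjusted p = 0.34) and dendritic-like cells (16.7% ± 6.21 against 8.22% ± 3.46, adjusted p = 0.27) did not pass either. The dendritic-like difference turned to -41.8 points with stricter cell filters and -26.6 points in the clustering without stress genes (1 normal library left in each), and the monocyte or macrophage-like one to -11.4 points at the lower clustering resolution and -8.59 points without normal replicate 1 (1 normal library left). Without replicate 1 the follicular helper T-like and germinal center B-like differences turned as well (2.68 and 2.06 points). A naive or central memory sub-cluster of 1614 cells, led by KLF2 with the heat shock gene HSPA6, came 86.1% from normal tissue and 84.6% from a single library. The regulatory T-like difference missed the threshold without normal replicate 1, 2 or 3 (13.1, 14.3 and 11.6 points, permutation adjusted p = 0.083, 0.056 and 0.15). Within the 3 paired donors the differences were 11.1, 12.2 and -38.8 points for CD8, regulatory and naive or central memory T-like cells (exact sign-flip adjusted p = 0.62 for each), and against the 9 tumors of the same label style 22.1, 12.3 and -45.3 points.

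Gene expression in T or NK-like cells, summed per library, differed for 1975 of 11590 genes tested, 919 higher and 1056 lower in tumors (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The sum mixes subsets whose shares differed, so composition and expression are not separated. Some cytotoxicity, exhaustion and type I interferon genes rose, and some naive and recirculating genes fell. None of these lists passed with an estimated correlation (adjusted p = 0.12 each). GZMB (ENSG00000100453, chromosome 14, 24630954 to 24634267), which encodes the cytotoxic protease granzyme B, averaged 568 ± 348 CPM in tumor and 22.7 ± 2.95 CPM in normal libraries (log2 fold change 4.65, SE 0.72, adjusted p = 0.0015), with 14 of 14 tumors above every normal library. Of the cytotoxicity list, of which 3 members also named these cells, 9 of 15 members rose and 0 fell, or 10 and 1 adjusted over the list alone. As a set they had a median of 1.47 (camera adjusted p = 8.0e-08, adjusted p = 0.12 with an estimated correlation). Of the list of exhaustion and tumor reactivity genes, 7 of 15 members rose and 1 fell, or 8 and 1 adjusted over the list alone. The list's median was 1.06 (camera adjusted p = 3.5e-06, adjusted p = 0.12 with an estimated correlation). Its members LAYN and ENTPD1, which encode a hyaluronan receptor and the ectonucleotidase CD39, rose by 3.80 and 3.0 on the log2 scale (adjusted p = 0.0015 and 0.0015). TNFRSF9, the costimulatory receptor 4-1BB, averaged 97.2 ± 35.9 CPM in tumor and 12.2 ± 8.75 CPM in normal libraries (log2 fold change 2.95, SE 0.43, adjusted p = 0.0015). Of the regulatory T cell activation list, 10 of 16 members rose and 0 fell, or 14 and 0 adjusted over the list alone. The median over the members was 1.93 (camera adjusted p = 6.5e-13, adjusted p = 0.077 with an estimated correlation). Of the type I interferon list, 13 of 25 members rose and 0 fell, or 18 and 0 adjusted over the list alone. The list median was 1.02 (camera adjusted p = 2.5e-09, adjusted p = 0.12 with an estimated correlation). IFI27 rose by 4.73 and IFI6 by 2.32 (adjusted p = 0.0028 and 0.0021). Among antigen presentation genes, HLA-DRA and HLA-DPA1 of MHC class II rose by 2.22 and 2.11, and the peptide transporter gene TAP1 by 0.81. Of the MHC class II list, 5 of 9 members rose and 0 fell, or 7 and 0 adjusted over the list alone. Their median stood at 1.46 (camera adjusted p = 3.5e-06, adjusted p = 0.12 with an estimated correlation). CXCR6, a homing receptor of tissue-resident T cells, rose by 2.34, and the glycolytic gene GAPDH by 1.16. Of the naive and recirculating list, of which 1 member also named these cells, 0 of 14 members rose and 6 fell, or 0 and 7 adjusted over the list alone. The median of these genes was -0.95 (camera adjusted p = 2.6e-06, adjusted p = 0.12 with an estimated correlation). TCF7, a transcription factor of naive and memory T cells, averaged 60.8 ± 26.2 CPM in tumor and 186 ± 17.3 CPM in normal libraries (log2 fold change -1.61, SE 0.32, adjusted p = 0.0047). LEF1 (-1.38), the early activation gene CD69 (-1.36), SERINC5 (-1.63) and the diacylglycerol kinase gene DGKA (-1.42) were also lower. Epithelial genes moved with these groups (median 3.20, adjusted p = 3.5e-06, adjusted p = 0.12 with an estimated correlation), as did the dissociation and heat stress list (median -0.94, adjusted p = 0.048, adjusted p = 0.62 with an estimated correlation, adjusted p = 0.62 with the donor block). With no normalization factor, the split was 1374 higher and 617 lower, and the median of all genes moved by 0.16 on the log2 scale. The T or NK-like count was 18 with the donor block, 755, 1304 and 1202 without normal replicates 1, 2 and 3, 864 against the 9 tumors of the normal label style, 0 unpaired in the paired donors, and 1046 with each cell thinned to 1000 UMIs. Of the 16 T or NK-like genes named, 1 passed with the block and 16, 16 and 15 without each in turn.

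CD8 T-like cells differed for 250 of 7979 genes tested, 91 higher and 159 lower in tumors in edgeR's test, with ENTPD1, GZMB and IFI27 among the genes that rose. Sub-clusters 1 (led by DKK3, CD8A and GZMK) and 4 (CD8A, VCAM1) held 58.7% of its tumor cells, and 13 (CCL4L2, TNFSF9 and the heat shock genes HSPA6 and DNAJB1) and 17 (GZMK, KLRG1) 79.8% of its normal cells. ENTPD1 (ENSG00000138185, chromosome 10, 95711779 to 95869695) averaged 101 ± 41.5 CPM in tumor and 3.94 ± 2.62 CPM in normal libraries (log2 fold change 4.86, SE 0.92, adjusted p = 0.015), GZMB 1363 ± 828 CPM in tumor and 160.0 ± 17.6 CPM in normal libraries (log2 fold change 3.09, SE 0.63, adjusted p = 0.017). LAYN rose by 3.96 and RBPJ, a nuclear effector of Notch signaling, by 1.84. Of the exhaustion and tumor reactivity list, 3 of 15 members rose and 0 fell, or 9 and 0 adjusted over the list alone. The median here was 1.12 (camera adjusted p = 2.5e-09, adjusted p = 0.073 with an estimated correlation). Of the cytotoxicity list, of which 9 members also named these cells, 2 of 15 rose and 0 fell (2 and 3 adjusted over the list alone), and the set did not pass (median -0.02, adjusted p = 0.94). Among type I interferon genes in these cells, 5 of 25 members rose and 0 fell, or 9 and 0 adjusted over the list alone. Members had a median of 1.04 (camera adjusted p = 2.8e-12, adjusted p = 0.073 with an estimated correlation). IFI27 (4.97) and the antiviral GTPase gene MX1 (1.97) rose. GAPDH rose by 1.30. Of the glycolysis and hypoxia list, 3 of 12 members rose and 0 fell, or 4 and 0 adjusted over the list alone. As a set they had a median of 0.55 (camera adjusted p = 2.7e-05, adjusted p = 0.054 with an estimated correlation). KRT86, a hair keratin gene with near-identical relatives, had the largest rise of those named (log2 fold change 7.04, SE 1.53, adjusted p = 0.024), beside a higher epithelial list (median 3.14, adjusted p = 9.8e-07, adjusted p = 0.073 with an estimated correlation). CD69 (-1.38), the IgM receptor gene FCMR (-2.12) and TC2N (-1.55) fell, beside a lower dissociation and heat stress list (median -1.51, adjusted p = 2.7e-05, adjusted p = 0.40 with an estimated correlation). With no normalization factor, 176 higher and 89 lower passed, and the median of all genes moved by 0.17. The CD8 T-like count was 12 with the donor block, 138, 216 and 0 without normal replicates 1, 2 and 3, 35 against the 9 tumors of the normal label style, 0 unpaired in the paired donors, 392 by DESeq2, and 112 with thinned cells. Of the 11 CD8 T-like genes named, 6 passed with the block and 7, 10 and 0 without each in turn.

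Regulatory T-like cells differed for 125 of 7575 genes tested, 54 higher and 71 lower in tumors in edgeR's test, with TNFRSF9, CXCR3 and SOX4 among the genes that rose and LAG3 among those that fell. Of the regulatory T cell activation list, of which 9 members also named these cells, 5 of 15 members rose and 0 fell, or 10 and 0 adjusted over the list alone. The list's median was 1.16 (camera adjusted p = 1.6e-13, adjusted p = 0.0077 with an estimated correlation). TNFRSF9 rose by 2.11 (adjusted p = 0.011), the checkpoint receptor gene TIGIT by 0.90, and CXCR3, which encodes the receptor of interferon-induced chemokines, by 2.63 (adjusted p = 0.0036). The transcription factor gene SOX4 (ENSG00000124766, chromosome 6, 21592768 to 21598619) averaged 250.1 ± 102 CPM in tumor and 15.0 ± 14.1 CPM in normal libraries (log2 fold change 4.10, SE 0.65, adjusted p = 0.0036). LAG3, another checkpoint receptor gene, averaged 92.1 ± 37.8 CPM in tumor and 745 ± 807 CPM in normal libraries (log2 fold change -3.04, SE 0.44, adjusted p = 0.0028), with 9 of 14 tumors below every normal library. Its normal SD exceeded the normal mean, so the size of this fall leaned on the highest normal library. IL6ST (-1.21) and CD69 (-1.45) fell, and LGALS3 (1.74), CXCR6 (1.48) and the interferon-induced gene ISG15 (1.67) rose. Of the cytotoxicity list, of which 3 members also named these cells, 1 of 9 members rose and 0 fell, or 3 and 0 adjusted over the list alone. The median over the members was 3.39 (camera adjusted p = 1.5e-06, adjusted p = 0.042 with an estimated correlation). Of the naive and recirculating list, of which 1 member also named these cells, 0 of 13 members rose and 0 fell, or 0 and 5 adjusted over the list alone. The list median was -0.71 (camera adjusted p = 1.5e-06, adjusted p = 0.019 with an estimated correlation). Among type I interferon genes, 3 of 25 members rose and 0 fell, or 9 and 0 adjusted over the list alone. Their median stood at 0.86 (camera adjusted p = 1.6e-07, adjusted p = 0.24 with an estimated correlation). Sub-cluster 0 held 63.4% of the tumor cells and sub-cluster 9 45.7% of the normal cells, both led by FOXP3. The epithelial list was higher here too (median 3.37, adjusted p = 1.5e-06, adjusted p = 0.16 with an estimated correlation) and the dissociation and heat stress list lower (median -0.89, adjusted p = 0.00084, adjusted p = 0.44 with an estimated correlation, adjusted p = 0.079 with the donor block). The regulatory T-like count was 13 with the donor block, 18, 2 and 64 without normal replicates 1, 2 and 3, 63 against the 9 tumors of the normal label style, 1 unpaired in the paired donors, 236 by DESeq2, 64 with at least 50 cells per library, and 56 with thinned cells. Of the 10 regulatory T-like genes named, 4 passed with the block and 5, 1 and 6 without each in turn.

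Follicular helper T-like cells, which help B cells in germinal centers, differed for 45 of 5490 genes tested, 22 higher and 23 lower in tumors in edgeR's test over 12 tumor and 2 normal libraries. Sub-cluster 11, led by PTPN13 and CXCL13, held 72.4% of the tumor cells, and sub-cluster 16, with TOX2 and IL6R among its leading genes, 98.0% of the normal cells. CXCR6 (5.61), LMO4 (5.19, adjusted p = 0.00051) and the interferon-induced genes IFI44 (3.31) and LY6E (2.08) rose, and CD38, an ectoenzyme gene of activated and germinal center cells, fell (-2.39). Of the type I interferon list, 3 of 19 members rose and 0 fell, or 9 and 0 adjusted over the list alone. The median of these genes was 1.59 (camera adjusted p = 3.7e-09, adjusted p = 0.21 with an estimated correlation). Epithelial genes as a list were higher (median 3.97, adjusted p = 6.1e-06, adjusted p = 0.21 with an estimated correlation). In naive or central memory T-like cells, edgeR called 0 of 7839 genes (757 at an unadjusted p under 0.05, 23 by DESeq2, and 21 with the donor as a block), where sub-cluster 3 held 55.8% of the tumor cells and sub-clusters 6 and 5 80.7% of the normal cells. Their exhaustion and tumor reactivity list was lower as a set (median -0.56, adjusted p = 0.00085, adjusted p = 0.18 with an estimated correlation). Without a normalization factor, 24 higher and 10 lower passed in follicular helper T-like cells, and the median of all genes moved by 0.12. The follicular helper T-like count was 0 with the donor block, 4 against the 9 tumors of the normal label style, 0 unpaired in the paired donors, 93 by DESeq2, 82 with no filter on low counts, 4 with at least 50 cells per library, and 27 with no doublet removal. Leaving out either of its 2 normal libraries, replicates 1 and 2, left 1, so no count is given here. Of the 5 follicular helper T-like genes named, 0 passed with the block.

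In B-like cells no single gene passed, and the type I interferon list was higher as a set with the preset correlation but not with an estimated one (adjusted p = 0.23). edgeR called 0 of 10870 genes in B-like cells (1078 at an unadjusted p under 0.05, 51 by DESeq2 and 4 with the donor block), 0 of 5777 in germinal center B-like cells (334 unadjusted, 4 by DESeq2 and 1 with the block) and 0 of 8624 in memory B-like cells (1122 unadjusted, 21 by DESeq2 and 0 with the block). Of the type I interferon list in B-like cells, 0 of 25 members rose and 0 fell, or 9 and 0 adjusted over the list alone. The median here was 0.77 (camera adjusted p = 1.2e-09, adjusted p = 0.23 with an estimated correlation). Of the germinal center program, which B cells run while they mutate and select their receptors, 0 of 14 members rose and 0 fell, or 0 and 1 adjusted over the list alone. Members had a median of -0.74 (camera adjusted p = 0.00067, adjusted p = 0.54 with an estimated correlation, adjusted p = 0.12 with the donor block). The epithelial list was higher (median 3.44, adjusted p = 4.6e-13, adjusted p = 0.058 with an estimated correlation). In naive B-like cells 4 of 8738 genes tested, 1 higher and 3 lower in tumors, passed, among them S100A11, which encodes a calcium-binding protein (log2 fold change 1.60, SE 0.28, adjusted p = 0.031). Sub-clusters 1 and 3 held 38.1% of the tumor and 40.9% of the normal naive B-like cells, 0 and 2 33.7% and 46.8% of the memory B-like, and 9 and 14 41.5% and 40.7% of the germinal center B-like cells, with 62.5% of number 2 and 69.4% of number 14 from 1 library each. Leaving out normal replicates 1, 2 and 3 gave 3, 6 and 0 genes in naive B-like cells, 0, 0 and 4 in B-like cells, 0, 0 and 1 in germinal center B-like cells and 1, 12 and 20 in memory B-like cells. The donor block gave 162 in naive B-like cells, and the tumors of the normal label style 0, with S100A11 passing with the block and without normal replicate 1 but not without replicates 2 and 3.

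Plasma-like cells, which secrete antibody, differed for 10 of 6827 genes tested, 3 higher and 7 lower in tumors in edgeR's test. IFI27 (log2 fold change 6.0, SE 1.07, adjusted p = 0.030) and LY6E (1.17), both interferon-induced, rose, and RGS13, a germinal center gene, fell (-2.83). For the type I interferon list in plasma-like cells, 2 of 19 members rose and 0 fell, or 4 and 0 adjusted over the list alone. As a set they had a median of 0.48 (camera adjusted p = 5.8e-06, adjusted p = 0.12 with an estimated correlation). The epithelial list was higher (median 2.85, adjusted p = 1.4e-06, adjusted p = 0.12 with an estimated correlation). In the plasma-like class, cluster 10 held 66.8% of the tumor cells and cluster 24 52.1% of the normal cells. Without a normalization factor, 1 higher and 16 lower passed, and the median of all genes moved by -0.10. The plasma-like count was 19 with the donor block, 0, 5 and 3 without normal replicates 1, 2 and 3, 1 against the 9 tumors of the normal label style, 2 unpaired in the paired donors, 129 by DESeq2, 42 with no filter on low counts, 16 with at least 5 CPM in 3 libraries, 22 with the metastasis added, and 1 with thinned cells. Of the 3 plasma-like genes named, 1 passed with the block and 0, 1 and 1 without each in turn.

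Myeloid-like cells differed for 311 of 9932 genes tested, 158 higher and 153 lower in tumors in edgeR's test, with CXCL9 and TAP1 among the genes that rose and JUN among those that fell. CXCL9 (ENSG00000138755, chromosome 4, 76001275 to 76007488), a chemokine gene induced by interferon gamma, averaged 416 ± 276 CPM in tumor and 24.5 ± 20.9 CPM in normal libraries (log2 fold change 4.26, SE 0.96, adjusted p = 0.025). IFI27 rose by 6.89 (adjusted p = 0.022). Of the type I interferon list, 7 of 25 members rose and 0 fell, or 13 and 0 adjusted over the list alone. The list's median was 1.34 (camera adjusted p = 2.0e-15, adjusted p = 0.060 with an estimated correlation). Of the interferon gamma and CXCR3 ligand list, 5 of 16 members rose and 0 fell, or 9 and 0 adjusted over the list alone. The median over the members was 1.65 (camera adjusted p = 5.4e-12, adjusted p = 0.044 with an estimated correlation). Of the MHC class I presentation list, 6 of 16 members rose and 0 fell, or 11 and 0 adjusted over the list alone. The list median was 0.82 (camera adjusted p = 1.3e-09, adjusted p = 0.044 with an estimated correlation). TAP1 rose by 1.65, and B2M, the invariant chain of MHC class I, averaged 11777 ± 2247 CPM in tumor and 5815 ± 213 CPM in normal libraries. JUN (-2.26), EGR1 (-2.86) and the chaperone gene HSP90AA1 (-1.66) fell. Of the dissociation and heat stress list, 0 of 18 members rose and 4 fell, or 0 and 10 adjusted over the list alone. Their median stood at -1.17 (camera adjusted p = 9.6e-15, adjusted p = 0.030 with an estimated correlation). CD52, a surface glycoprotein gene of leukocytes, fell by 1.61 (adjusted p = 0.00092). Epithelial genes as a list were higher (median 2.15, adjusted p = 0.0014, adjusted p = 0.25 with an estimated correlation). The normal libraries held 52, 37 and 75 myeloid-like cells, and cluster 20, led by CCL18, APOC1 and C1QA, held 43.8% of the tumor cells of this class, against 41.5% of the normal cells in cluster 32, which LYZ, S100B, CCL22 and CD1A led. With upper-quartile normalization, the split was 118 higher and 256 lower, and the median of all genes moved by -0.12. The myeloid-like count was 5 with the donor block, 218, 83 and 68 without normal replicates 1, 2 and 3, 111 against the 9 tumors of the normal label style, 0 unpaired in the paired donors, 83 with at least 50 cells per library, and 96 with thinned cells. Of the 8 myeloid-like genes named, 1 passed with the block and 5, 5 and 4 without each in turn.

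Within the monocyte or macrophage-like subset, edgeR's test called 401 of 8979 genes tested, 189 higher and 212 lower in tumors. APOC1, an apolipoprotein gene of lipid-laden macrophages, averaged 2470 ± 1312 CPM in tumor and 313 ± 388 CPM in normal libraries (log2 fold change 2.94, SE 0.80, adjusted p = 0.045). NR1H3, the liver X receptor gene of cholesterol handling, rose by 2.88, and the complement gene C2 by 3.35 (adjusted p = 0.0019). Of the lipid-associated and complement macrophage list, of which 6 members also named these cells, 4 of 16 members rose and 0 fell, or 6 and 0 adjusted over the list alone. The median of these genes was 1.23 (camera adjusted p = 3.8e-09, adjusted p = 0.056 with an estimated correlation). CXCL9 (4.76) and ISG15 (2.49) rose, and FSCN1, an actin-bundling gene of mature dendritic cells, fell (-1.83). In the type I interferon list, 7 of 25 members rose and 0 fell, or 15 and 0 adjusted over the list alone. The median here was 1.5 (camera adjusted p = 8.7e-15, adjusted p = 0.059 with an estimated correlation). Sub-cluster 0, led by APOE, held 17.9% of the tumor cells, and sub-cluster 5, with the stress genes EGR1 and HSPA6 among its leading genes, 48.7% of the normal cells. The dissociation and heat stress list was lower (median -1.30, adjusted p = 7.7e-13, adjusted p = 0.038 with an estimated correlation). The monocyte or macrophage-like count was 30 with the donor block, 313, 133 and 100 without normal replicates 1, 2 and 3, 162 against the 9 tumors of the normal label style, 0 unpaired in the paired donors, and 91 with thinned cells. Of the 6 monocyte or macrophage-like genes named, 2 passed with the block and 4, 4 and 2 without each in turn.

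Fibroblast or mural-like cells differed for 612 of 8617 genes tested, 295 higher and 317 lower in tumors in edgeR's test. The matrix-remodeling gene MMP11 and the interferon-induced gene ISG15 were among those that rose, and the chemokine genes CXCL12 and CCL21 among those that fell. MMP11 (ENSG00000099953, chromosome 22, 23768226 to 23784316), a stromal matrix metalloproteinase gene, averaged 1537 ± 1283 CPM in tumor and 48.4 ± 61.5 CPM in normal libraries (log2 fold change 5.03, SE 1.27, adjusted p = 0.029). COL10A1 (4.23), CTHRC1 (3.83) and LRRC15 (3.19), markers of fibroblasts in carcinomas, rose as well. Of the cancer-associated fibroblast list, 7 of 16 members rose and 0 fell, or 14 and 0 adjusted over the list alone. Members had a median of 2.5 (camera adjusted p = 4.7e-13, adjusted p = 0.099 with an estimated correlation). The basement membrane collagen gene COL4A1 rose by 2.25 and GAPDH by 1.08. ISG15 (3.21) and IFI27 (2.73) rose. Among interferon genes, 11 of 25 members rose and 0 fell, or 19 and 0 adjusted over the list alone. As a set they had a median of 1.39 (camera adjusted p = 2.5e-15, adjusted p = 0.099 with an estimated correlation). B2M rose by 1.26. Of the MHC class I list, 8 of 16 members rose and 0 fell, or 13 and 0 adjusted over the list alone. The list's median was 1.0 (camera adjusted p = 8.7e-09, adjusted p = 0.12 with an estimated correlation). CXCL12, the chemokine that retains cells in stromal niches, averaged 445 ± 309.6 CPM in tumor and 2454 ± 430.0 CPM in normal libraries (log2 fold change -2.46, SE 0.46, adjusted p = 0.0079), and CCL21, which draws CCR7-bearing lymphocytes, 127 ± 114 CPM in tumor and 2816 ± 2737 CPM in normal libraries (log2 fold change -4.46, SE 0.87, adjusted p = 0.010). SRPX also fell (-3.05). Of the reticular and lymphoid stroma list, of which 2 members also named these cells, 0 of 10 members rose and 2 fell, or 0 and 2 adjusted over the list alone. The median over the members was -0.80 (camera adjusted p = 0.0085, adjusted p = 0.19 with an estimated correlation). The epithelial list was higher (median 3.81, adjusted p = 0.00016, adjusted p = 0.12 with an estimated correlation) and the dissociation and heat stress list lower (median -0.91, adjusted p = 1.6e-05, adjusted p = 0.12 with an estimated correlation). Cluster 31, with MMP11 and COL1A1 among its leading genes, held 49.3% of the tumor cells, and cluster 38, led by DCN and APOD, 72.1% of the normal cells. With no normalization factor, the split was 239 higher and 447 lower. The fibroblast or mural-like count was 12 with the donor block, 22, 284 and 370 without normal replicates 1, 2 and 3, 134 against the 9 tumors of the normal label style, 3 unpaired in the paired donors, 946 by DESeq2, and 98 with thinned cells. Of the 12 fibroblast or mural-like genes named, 3 passed with the block and 2, 6 and 10 without each in turn.

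Endothelial-like cells differed for 197 of 7768 genes tested, 103 higher and 94 lower in tumors in edgeR's test. ESM1 (ENSG00000164283, chromosome 5, 54977864 to 55022671), a gene of endothelial tip cells, rose by 6.89 on the log2 scale, from 3.0 ± 5.20 CPM to 391 ± 447 CPM (adjusted p = 0.047). COL4A1 (2.43), the insulin receptor gene INSR (2.37), the proteoglycan gene BGN (3.88), the metalloproteinase gene MMP2 (2.75) and CD276, which encodes the immune ligand B7-H3 (2.74), rose. Of the tip and angiogenic endothelium list, of which 2 members also named these cells, 4 of 14 members rose and 0 fell, or 12 and 0 adjusted over the list alone. The list median was 2.09 (camera adjusted p = 1.9e-11, adjusted p = 0.17 with an estimated correlation). KLF2, a flow-induced transcription factor gene (-1.70), TXNIP (-2.74) and the caveolar gene CAVIN2 (-2.22) fell. Of the MHC class II list, 0 of 9 members rose and 0 fell, or 0 and 0 adjusted over the list alone. Their median stood at -0.86 (camera adjusted p = 0.010, adjusted p = 0.64 with an estimated correlation). The type I interferon list did not pass (median 0.31, adjusted p = 0.76), and whether it differed from other classes was not tested. Epithelial genes as a list were higher (median 4.49, adjusted p = 0.0037, adjusted p = 0.35 with an estimated correlation) and the dissociation and heat stress list lower (median -0.91, adjusted p = 2.8e-07, adjusted p = 0.17 with an estimated correlation). The normal libraries held 102, 28 and 41 of these cells. Without a normalization factor, 189 higher and 63 lower passed, and the median of all genes moved by 0.12. The endothelial-like count was 6 with the donor block, 4, 31 and 145 without normal replicates 1, 2 and 3, 23 against the 9 tumors of the normal label style, 0 unpaired in the paired donors, 406 by DESeq2, and 24 with thinned cells. Of the 9 endothelial-like genes named, 0 passed with the block and 0, 4 and 4 without each in turn.

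Epithelial-like cells, the malignant cells of the tumors included, differed for 126 of 16757 genes tested, 63 higher and 63 lower in tumors in edgeR's test. The interferon-induced gene CXCL10 and the replication gene MCM4 were among those that rose, and MAL among those that fell. CXCL10 (ENSG00000169245, chromosome 4, 76021117 to 76023497), a chemokine gene induced by interferon, averaged 159 ± 127 CPM in tumor and 2.88 ± 4.49 CPM in normal libraries (log2 fold change 6.04, SE 1.28, adjusted p = 0.035). BST2 (2.27) and the immunoproteasome gene PSMB9 (2.02) rose. Of the interferon gamma and CXCR3 ligand list, 3 of 16 members rose and 0 fell, or 10 and 0 adjusted over the list alone. The median of these genes was 1.99 (camera adjusted p = 7.9e-12, adjusted p = 0.011 with an estimated correlation). Among type I interferon genes, 2 of 25 members rose and 0 fell, or 15 and 0 adjusted over the list alone. The median here was 1.91 (camera adjusted p = 4.0e-15, adjusted p = 0.064 with an estimated correlation). MCM4, a subunit of the replicative helicase, averaged 82.4 ± 13.2 CPM in tumor and 23.8 ± 11 CPM in normal libraries (log2 fold change 1.80, SE 0.26, adjusted p = 0.0041). MCM7 (1.52), the DNA methylation cofactor gene UHRF1 (2.24) and ATAD2 (1.74) rose. Of the list of E2F targets and HPV-associated genes, which E2F drives when viral E7 inactivates the retinoblastoma protein (1 member also named these cells), 3 of 20 members rose and 0 fell, or 18 and 0 adjusted over the list alone. Members had a median of 1.57 (camera adjusted p = 5.3e-23, adjusted p = 0.0083 with an estimated correlation). Of the cell cycle list, 1 of 20 members rose and 0 fell, or 8 and 0 adjusted over the list alone. As a set they had a median of 0.97 (camera adjusted p = 6.7e-11, adjusted p = 0.064 with an estimated correlation). MAL, a membrane trafficking gene of differentiated mucosa, fell by 5.88 on the log2 scale (22.5 ± 42.8 CPM in tumor and 1331 ± 1689 CPM in normal libraries). CRYAB (-3.22), HOPX (-3.60), CLIC3 (-3.20) and the cornified envelope gene PPL (-1.95) fell. Of the keratinocyte differentiation list, of which 2 members also named these cells, 0 of 21 members rose and 0 fell, or 0 and 5 adjusted over the list alone. The list's median was -2.07 (camera adjusted p = 2.5e-11, adjusted p = 0.17 with an estimated correlation). The dissociation and heat stress list was lower (median -0.45, adjusted p = 0.00020, adjusted p = 0.40 with an estimated correlation). The normal libraries held 67, 92 and 73 of these cells, of which 46.6% lay in cluster 40, led by KRT4, KRT14 and SPRR3, while the largest tumor cluster, number 6, came 99.9% from 1 library and held 12.1% of the tumor cells. The split was 39 higher and 82 lower with upper-quartile normalization and 124 higher and 53 lower with no factor, which moved the median of all genes by -0.14 and 0.19. The epithelial-like count was 0 with the donor block, 160, 19 and 1 without normal replicates 1, 2 and 3, 3 against the 9 tumors of the normal label style, 0 unpaired in the paired donors, 301 by DESeq2, and 54 with thinned cells. Of the 12 epithelial-like genes named, 0 passed with the block and 11, 2 and 0 without each in turn.

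**Figure D2:**
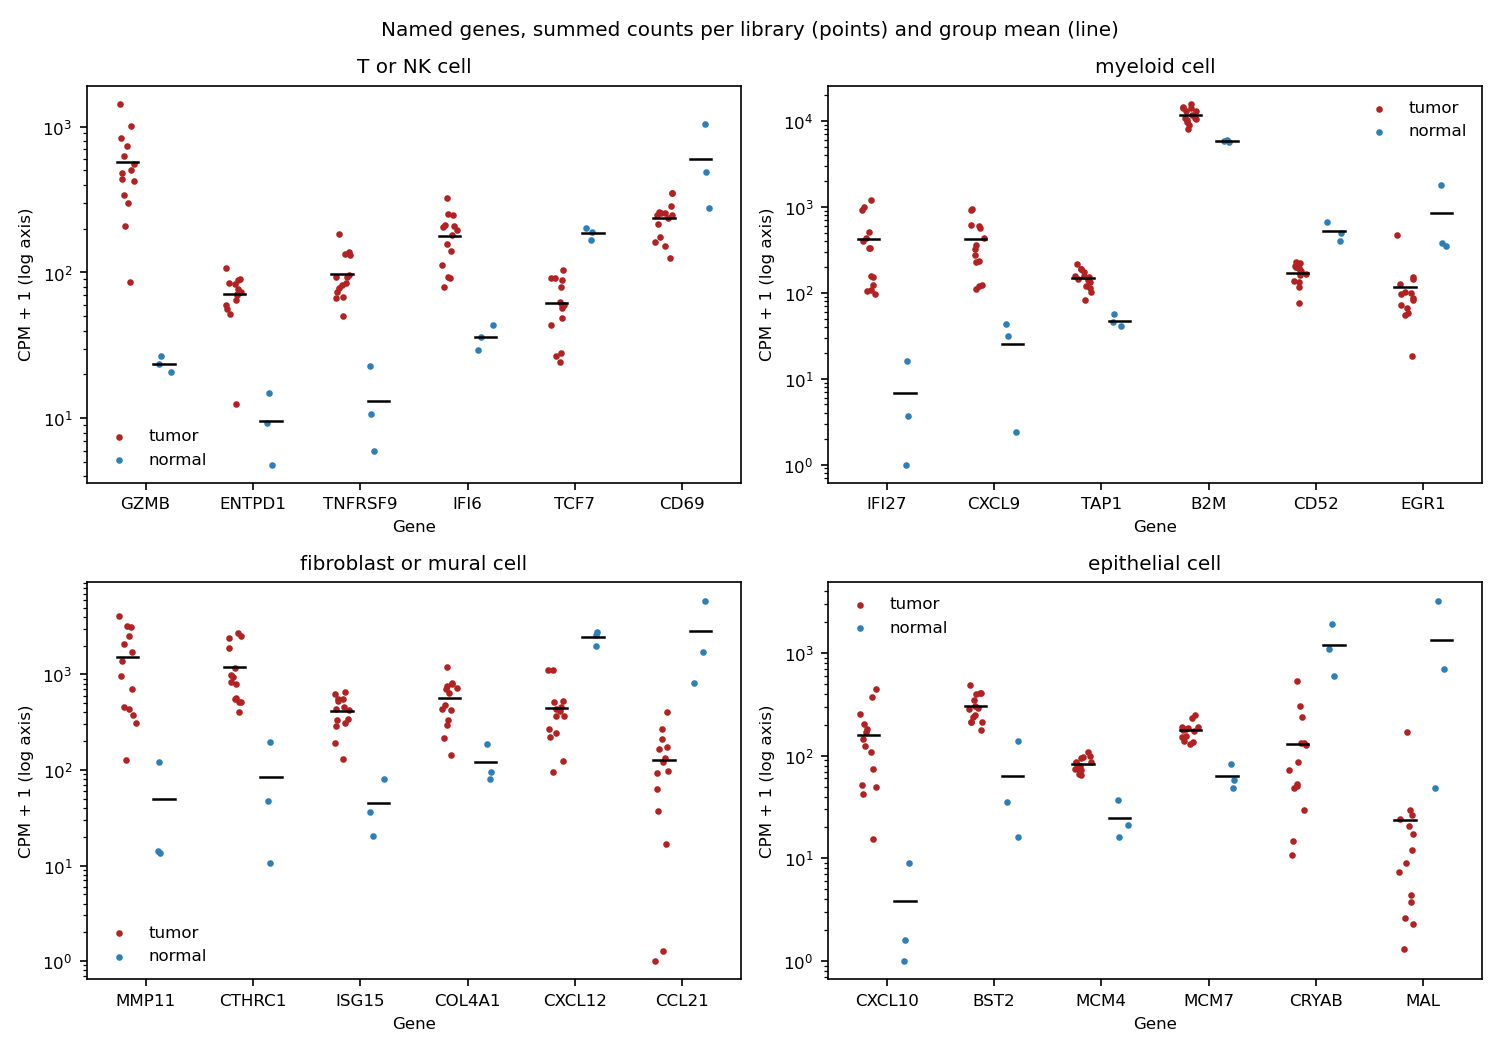
CPM plus 1 (vertical axes, log scale) of 6 named genes in each of 4 classes; points are libraries (tumor in red, normal in blue) and black lines the group means. GZMB in T or NK-like cells averaged 568 CPM in tumors and 22.7 CPM in normal libraries, and CXCL12 in fibroblast or mural-like cells 445 and 2454 CPM.

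In the sum of all cells, which mixes composition with expression, edgeR's test called 3406 of 18615 genes tested, 1595 higher and 1811 lower in tumors. CDKN2A (ENSG00000147889, chromosome 9, 21967753 to 21995301), whose product p16 accumulates in HPV-driven carcinomas, averaged 687 ± 439.8 CPM in tumor and 16.6 ± 2.84 CPM in normal libraries (log2 fold change 5.37, SE 0.82, adjusted p = 0.0020). The meiotic genes SMC1B (4.71) and SYCP2 (4.07), the simple-epithelium keratin gene KRT8 (3.67) and the complement gene C1QC (3.43) rose. The B cell and germinal center genes CR2 (-4.15), RGS13 (-4.03), MEF2B (-3.40), SERPINA9 (-4.81), LTB (-2.12) and CD37 (-2.20) fell. Of the germinal center program, 0 of 14 members rose and 8 fell, or 0 and 12 adjusted over the list alone. The median over the members was -1.99 (camera adjusted p = 4.7e-06, adjusted p = 0.41 with an estimated correlation). Of the basal keratinocyte list, 9 of 14 members rose and 0 fell, or 10 and 0 adjusted over the list alone. The list median was 2.78 (camera adjusted p = 4.7e-06, adjusted p = 0.41 with an estimated correlation). Of the E2F and HPV-associated list, 7 of 20 members rose and 1 fell, or 8 and 1 adjusted over the list alone. Their median stood at 0.97 (camera adjusted p = 1.2e-05, adjusted p = 0.47 with an estimated correlation). Of the lipid-associated macrophage list, 6 of 16 members rose and 0 fell, or 6 and 0 adjusted over the list alone. The median of these genes was 2.25 (camera adjusted p = 2.0e-05, adjusted p = 0.41 with an estimated correlation). The split was 1314 higher and 2209 lower with upper-quartile normalization and 1774 higher and 1531 lower with no factor, which moved the median of all genes by -0.11 and 0.12. The all-cell count was 1316 with the donor block, 615, 1711 and 1325 without normal replicates 1, 2 and 3, and 3066 against the 9 tumors of the normal label style. Of the 11 all-cell genes named, 6 passed with the block and 5, 11 and 11 without each in turn.

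Across the 285 pairs of a class with a gene list, 136 passed with camera's preset correlation, 10 with an estimated correlation and 130 of 272 with the donor as a block. The type I interferon list was higher in T or NK-like, B-like, plasma-like, myeloid-like, fibroblast or mural-like and epithelial-like cells with the preset correlation, and in none of these with an estimated one (adjusted p from 0.060 to 0.23). Keratin and other epithelial genes in T or NK-like cells summed to 525 ± 355 CPM in tumors and 63.3 ± 38.5 CPM in normal tissue, against 33306 ± 11519 and 40105 ± 13482 CPM in epithelial-like cells.

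**Figure D3:**
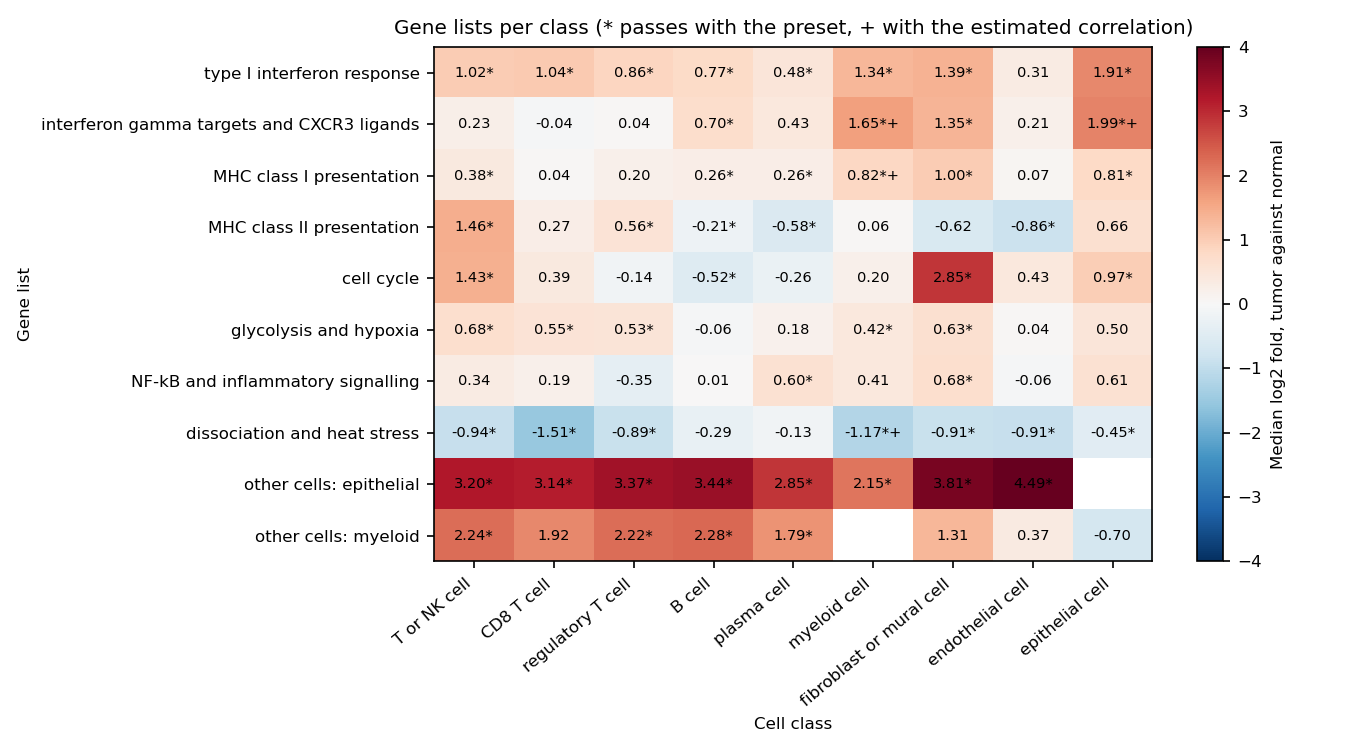
Median log2 fold change, tumor against normal (color and number), of 10 fixed gene lists (rows) in 9 cell classes (columns); * marks an adjusted p under 0.05 with camera's preset correlation and + also with an estimated correlation, and a blank cell a list of the class's own markers. The type I interferon list had medians from 0.31 in endothelial-like to 1.91 in epithelial-like cells.

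Whether gene lists varied together across the tumors was tested for 4 relations, and none passed. The type I interferon list in epithelial-like cells and that in myeloid-like cells gave Pearson r = 0.53 (permutation p = 0.053, adjusted p = 0.21) and Spearman rho = 0.42 (p = 0.14, adjusted p = 0.55) over 14 tumors, with r = 0.27 and rho = 0.24 without the 2 farthest tumors and 0.51 and 0.38 within the hyphen label style. For the same list in epithelial-like and T or NK-like cells the values were Pearson r = 0.37 (permutation p = 0.20, adjusted p = 0.39) and Spearman rho = 0.16 (p = 0.59, adjusted p = 0.83), with r = 0.25 and rho = 0.04 without the 2 farthest tumors and 0.42 and -0.02 within the hyphen label style. MHC class I genes in epithelial-like cells and exhaustion genes in CD8 T-like cells gave Pearson r = -0.03 (permutation p = 0.93, adjusted p = 0.93) and Spearman rho = 0.08 (p = 0.80, adjusted p = 0.83), with r = -0.10 and rho = 0.01 without the 2 farthest tumors and 0.28 and 0.33 within the hyphen label style. The percentage of germinal center B-like cells and that of follicular helper T-like cells gave Pearson r = -0.03 (permutation p = 0.93, adjusted p = 0.93) and Spearman rho = -0.07 (p = 0.83, adjusted p = 0.83) over 12 tumors, with r = 0.13 and rho = 0.09 without the 2 farthest tumors and 0.06 and 0.03 within the hyphen label style. Permutation tests used 100000 resamples, and the other label style held 5 tumors, under the 6 required for a correlation.

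The metastasis was set against the primary tumor of the same donor. With 1 library each there is no test, and the intervals (95%, exact binomial for shares and counting intervals for ratios) cover counting error only. Epithelial-like cells made up 57.0% (55.4 to 58.7) of the metastasis and 37.8% (36.0 to 39.6) of the primary tumor. B-like cells made up 5.95% (5.19 to 6.77) and 1.47% (1.07 to 1.98). T or NK-like (25.2% (23.8 to 26.6) against 31.1% (29.4 to 32.8)), plasma-like (2.37% (1.90 to 2.93) against 7.43% (6.51 to 8.45)), myeloid-like (5.42% (4.70 to 6.21) against 9.52% (8.48 to 10.6)), fibroblast or mural-like (3.29% (2.73 to 3.93) against 10.2% (9.17 to 11.4)) and endothelial-like cells (0.0838% (0.0173 to 0.245) against 1.61% (1.19 to 2.14)) were lower in the metastasis, as was the regulatory T-like share of T or NK-like cells (20.4% (17.8 to 23.2) against 34.5% (31.4 to 37.7)). In epithelial-like cells (2043 and 1103 cells, 29398827 and 22476531 UMIs), the glycolysis and hypoxia list was higher in the metastasis (median log2 ratio 0.66, percentile 100 among 10000 random lists of like expression). The basal keratinocyte list (median log2 ratio -0.48, percentile 0), the keratinocyte differentiation list (median log2 ratio -0.38, percentile 0.200), the epithelial to mesenchymal transition list (median log2 ratio -0.44, percentile 0.960) and the type I interferon list (median log2 ratio -0.33, percentile 0.600) were lower, and the list of E2F targets and HPV-associated genes lay near the middle (median log2 ratio 0.03, percentile 73.3). The dissociation and heat stress list (median log2 ratio -0.22, percentile 1.24), the mitochondrial list (median log2 ratio -0.28, percentile 1.26), the stroma list (median log2 ratio -1.17, percentile 1.37) and the myeloid list (median log2 ratio -0.84, percentile 0.280) were also lower. The plasma and B cell list was higher (median log2 ratio 1.0, percentile 100), but with each cell thinned to 1000 UMIs its median over 5 genes was -0.30 (percentile 35.8). Among single genes, the hypoxia-induced genes CA9 and NDUFA4L2 had log2 ratios of 4.36 (3.95 to 4.83) and 3.88 (3.80 to 3.95), the hyaluronan synthase gene HAS2 5.12 (4.26 to 6.34) and the kinase gene PNCK 4.60 (4.21 to 5.05). IFNL1, a type III interferon gene, had 157 UMIs against 0, at least 40-fold higher against a floor of 3 UMIs, and KRTDAP 64 against 0, at least 16.3-fold higher. The 95% counting intervals of their log2 ratios began at 5.01 and 3.69, and at -0.01 and -1.59 with thinned cells, which did not exclude 0. The germline genes PAGE1, SOHLH1, GTSF1 and MAGEA10 had 0 UMIs in the metastasis and were at least 186, 173, 164 and 62.8-fold lower against the same floor, with intervals that ended at -7.23, -7.13, -7.05 and -5.66. The water channel gene AQP5 (-9.25 (-15.14 to -7.35)) and the antimicrobial gene S100A7 (-8.48 (-8.95 to -8.08), 46 against 12722 UMIs) were lower. The interval left out 0 for 8513 genes, 3191 higher and 5322 lower, and for 1997 with thinned cells, 1009 higher and 988 lower, where 4 of the 20 most extreme genes were shared.

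**Figure D4:**
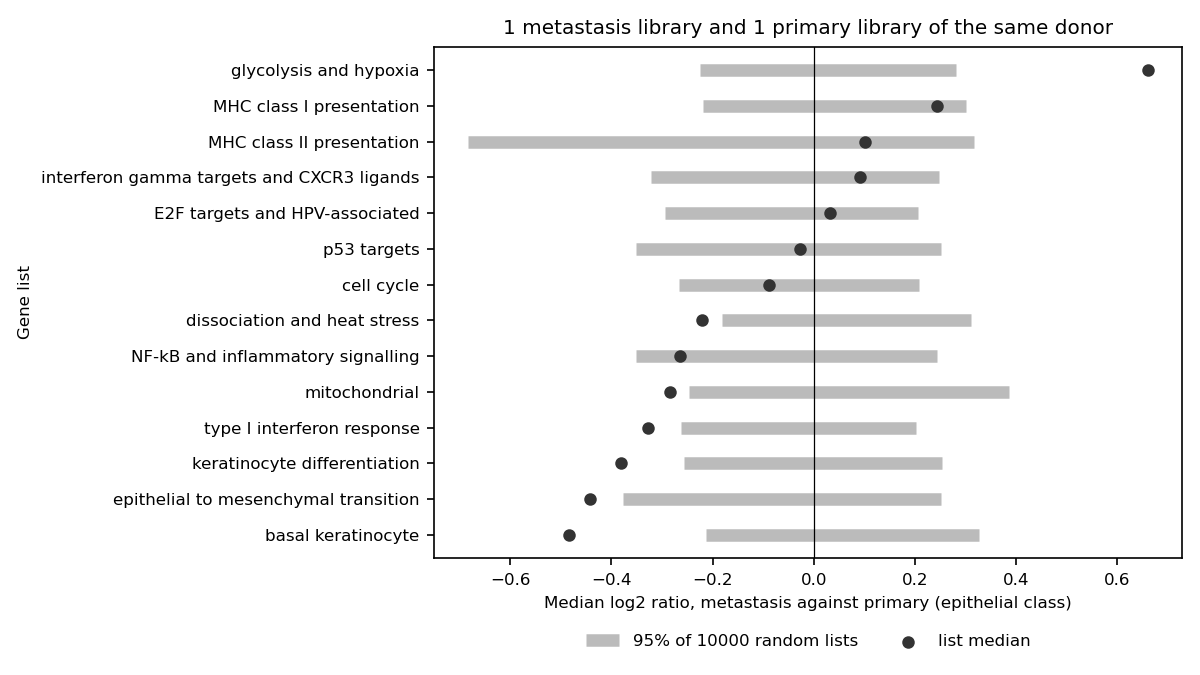
Median log2 ratio of metastasis to primary tumor in epithelial-like cells (horizontal axis, dots) for each gene list (vertical axis), with gray bars for the middle 95% of 10000 random lists matched on expression; 1 library per tissue from 1 donor. The glycolysis and hypoxia list stood at 0.66 and the basal keratinocyte list at -0.48.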

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

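The comparison in this part was chosen after the cluster was seen. An unnamed cluster, led by immunoglobulin (IGHG1, IGHA1, JCHAIN) and epithelial genes (KRT15, DSP, CLDN4, S100A7), held 10.4% of cells of tumor replicate 12 (824 of 7897). Its cells enter only all-cell sums and broad share denominators. The next tumor had 0.0798% and the highest normal library 0.0277%.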

How the results depend on the processing

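The clustering without stress genes and the mast-like class without a cluster of 1 library were chosen after the data were seen, and the other alternatives before. No named gene turned direction in 1565 values over alternatives (1124 past the threshold, 441 not). These genes were picked on the same libraries, so a turn was unlikely. Of counts of changed genes, 122 lay within 1.5 times the main count, 78 below and 47 above. Of share differences, 208 kept direction and side of the threshold, 16 turned, 8 fell back and 3 gained it. The donor block and the fit on 3 donors use fewer libraries, and thinning fewer UMIs, and the other causes were not tested. In counts simulated from the libraries, edgeR found 62.3% to 95.2% of 4-fold changes in the classes other than epithelial-like cells (24.7%) and all cells (44.7%).

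With the donor as a replicate block, changed genes numbered 18 in T or NK-like, 12 in CD8 T-like, 13 in regulatory T-like, 0 in follicular helper T-like, 21 in naive or central memory T-like, 4 in B-like, 1 in germinal center B-like, 162 in naive B-like, 19 in plasma-like, 5 in myeloid-like, 30 in monocyte or macrophage-like, 12 in fibroblast or mural-like, 6 in endothelial-like, 0 in epithelial-like and 1316 in all cells. In the unpaired fit on the 3 donors with both tissues, the counts were 0 in T or NK-like, 0 in CD8 T-like, 1 in regulatory T-like, 0 in follicular helper T-like, 0 in naive B-like, 2 in plasma-like, 0 in myeloid-like, 0 in monocyte or macrophage-like, 3 in fibroblast or mural-like, 0 in endothelial-like and 0 in epithelial-like. Against the tumors of the normal label style, genes past the threshold came to 864 in T or NK-like, 35 in CD8 T-like, 63 in regulatory T-like, 4 in follicular helper T-like, 1 in germinal center B-like, 0 in naive B-like, 1 in plasma-like, 111 in myeloid-like, 162 in monocyte or macrophage-like, 134 in fibroblast or mural-like, 23 in endothelial-like and 3 in epithelial-like. With each cell thinned to 1000 UMIs, changed genes numbered 1046 in T or NK-like, 112 in CD8 T-like, 56 in regulatory T-like, 1 in naive or central memory T-like, 1 in B-like, 1 in memory B-like, 0 in naive B-like, 1 in plasma-like, 96 in myeloid-like, 91 in monocyte or macrophage-like, 98 in fibroblast or mural-like, 24 in endothelial-like and 54 in epithelial-like. By DESeq2, the counts were 392 in CD8 T-like, 236 in regulatory T-like, 93 in follicular helper T-like, 23 in naive or central memory T-like, 51 in B-like, 4 in germinal center B-like, 21 in memory B-like, 16 in naive B-like, 129 in plasma-like, 946 in fibroblast or mural-like, 406 in endothelial-like and 301 in epithelial-like. With at least 50 cells per library, genes past the threshold came to 64 in regulatory T-like, 4 in follicular helper T-like, 2 in naive B-like, 83 in myeloid-like, 118 in monocyte or macrophage-like and 21 in endothelial-like. With no filter on low counts, changed genes numbered 82 in follicular helper T-like, 18 in naive or central memory T-like, 5 in B-like, 5 in germinal center B-like, 1 in memory B-like, 19 in naive B-like and 42 in plasma-like. With no doublet removal, the counts were 27 in follicular helper T-like, 2 in memory B-like and 2 in naive B-like. With upper-quartile normalization, genes past the threshold came to 1 in naive or central memory T-like and 1 in memory B-like. With at least 5 CPM in 3 libraries, changed genes numbered 2 in naive or central memory T-like, 1 in memory B-like and 16 in plasma-like. With the metastasis added, the counts were 1 in naive or central memory T-like, 1 in B-like, 1 in memory B-like and 22 in plasma-like. In the clustering without stress genes, genes past the threshold came to 2 in naive B-like. With no normalization factor, changed genes numbered 17 in plasma-like. Leaving out 1 normal library at a time gave 755 to 1304 in T or NK-like, 0 to 216 in CD8 T-like, 2 to 64 in regulatory T-like, 0 to 114 in follicular helper T-like, 0 to 4 in naive or central memory T-like, 0 to 4 in B-like, 0 to 1 in germinal center B-like, 1 to 20 in memory B-like, 0 to 6 in naive B-like, 0 to 5 in plasma-like, 68 to 218 in myeloid-like, 100 to 313 in monocyte or macrophage-like, 22 to 370 in fibroblast or mural-like, 4 to 145 in endothelial-like, 1 to 160 in epithelial-like and 615 to 1711 in all cells. The differences in share (points, tumor minus normal) without 1 normal library ran from -0.00822 to 0.248 for plasmacytoid dendritic-like, -0.338 to 0.964 for fibroblast or mural-like, -0.453 to 0.512 for endothelial-like, 11.6 to 14.3 for regulatory T-like, -5.69 to 2.68 for follicular helper T-like, -10.0 to 2.06 for germinal center B-like and -8.59 to 21 for monocyte or macrophage-like cells (both ends from 1 normal library). They were, with the donor as a replicate block -25.8 for B-like, -0.187 for plasma-like, -0.0108 for plasmacytoid dendritic-like, -1.94 for fibroblast or mural-like, 48.1 for epithelial-like, 11.1 for CD8 T-like, 12.2 for regulatory T-like and -38.8 for naive or central memory T-like cells. Under other settings the differences were as a percentage of immune cells 7.08 for T or NK-like, on the logit scale 1.24 for myeloid-like, -0.233 for fibroblast or mural-like and 0.548 for follicular helper T-like, against the tumors of the normal label style -1.40 for fibroblast or mural-like, at the higher resolution -6.0 for follicular helper T-like, at the lower clustering resolution -11.4 for monocyte or macrophage-like, with stricter cell filters -41.8 for dendritic-like, with no doublet removal 11.6 for dendritic-like, in the clustering without stress genes -26.6 for dendritic-like cells. The pairs of class and list past the threshold fell from 136 to 10 with an estimated correlation and 76 with fry. Of 133 pairs past the threshold and tested with the block, 104 passed with it in the same direction and 1 had the opposite direction. The relation of MHC class I with exhaustion genes turned to r = 0.275 within the hyphen label style, and that of germinal center B-like with follicular helper T-like shares to 0.131 without the 2 farthest tumors and 0.0562 within the style. Genes whose interval left out 0 in the metastasis numbered 1997 with thinned cells, against 8513. Both ends of the follicular helper T-like range of counts rest on 1 normal library (replicate 1 or 2). The dendritic-like differences with stricter filters and without stress genes also rest on 1. The unpaired fit and the block used the same 3 donors, so a call lost there is not shown to be a smaller effect.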

Other observations

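Thinning and label style were tried for the interferon genes after the result was seen. In plasma-like cells, the MHC class II list was lower in tumors (median -0.58, adjusted p = 0.00054, adjusted p = 0.12 with an estimated correlation), with 4 of 7 members lower adjusted over the list alone, and the NF-kB list was higher (median 0.60, adjusted p = 0.00036, adjusted p = 0.12 with an estimated correlation). The cell cycle list was higher in T or NK-like (median 1.43, adjusted p = 3.1e-06, adjusted p = 0.32 with an estimated correlation) and in fibroblast or mural-like cells (median 2.85, adjusted p = 0.0012, adjusted p = 0.23 with an estimated correlation, adjusted p = 0.82 with the donor block) and lower in B-like cells (median -0.52, adjusted p = 0.014, adjusted p = 0.67 with an estimated correlation, adjusted p = 0.28 with the donor block). Tissue residency genes were higher in T or NK-like cells (median 1.35, adjusted p = 0.0014, adjusted p = 0.12 with an estimated correlation). Neutrophil marker genes (FCGR3B, CSF3R) had a UMI in 0.628% ± 0.667 of the barcodes that failed the cell filters in tumors and in 0.529% ± 0.459 in normal libraries (SD), and 4 of 14 tumors lay above every normal library. Among the barcodes that passed the filters the values were 1.91% ± 0.956 and 0.639% ± 0.406, a difference that was not tested.

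Interferon-induced genes in T or NK-like cells summed to 2725 ± 811 CPM in tumors and 1129.6 ± 67.4 CPM in normal tissue. RNA released by epithelial-like cells, scaled by the keratin RNA found in the T or NK-like cells, would bring a median of 2.30% of the excess over the normal libraries (range 0.857% to 16.7%), which excludes it as the whole source. The list's median log2 fold was 1.02, 1.10 with cells thinned to 1000 UMIs and 1.09 against tumors of the normal label style. Thinning keeps expected gene proportions, so it does not test depth. Label style does not account for the rise. A tissue difference may account for it, as a hypothesis found and tested on the same data. Depth and handling that differed by tissue kind stay open.

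Epithelial genes in T or NK-like cells stood at 1.55 ± 0.734% of their level in epithelial-like cells in tumors and at 0.149 ± 0.0394% in normal tissue. Their levels in both classes correlated across 11 genes (not independent replicates) with a median r of 0.94 in tumors and 0.60 in normal libraries. Free epithelial RNA or doublets may bring these genes. T or NK-like cells with an epithelial UMI had 1.08 times the other UMIs of those without (tumor median), under the 1.5 set for doublets. A minority of doublets would not move this ratio.

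Other splits of the same libraries into groups of the same sizes were drawn 80 times per class, the real split included. In T or NK-like, CD8 T-like, regulatory T-like, naive B-like, plasma-like, myeloid-like, monocyte or macrophage-like, fibroblast or mural-like, endothelial-like, epithelial-like and all cells, 1 of the 80, the real one, called as many genes. The highest other splits called 727 (real 1975), 12 (real 250), 5 (real 125), 3 (real 4), 8 (real 10), 22 (real 311), 107 (real 401), 3 (real 612), 36 (real 197), 58 (real 126) and 81 (real 3406) genes, in that order. Ranking first of 80 splits, unadjusted over classes, argues weakly against chance allocation but does not exclude it. It stays open in naive B-like and plasma-like cells, with leads of only 1 and 2 genes. At its lowest without 1 normal library, the count lay below that of the highest other split in CD8 T-like (0 without replicate 3), regulatory T-like (2, replicate 2), naive B-like (0, replicate 3), plasma-like (0, replicate 1), monocyte or macrophage-like (100, replicate 3), endothelial-like (4, replicate 1) and epithelial-like cells (1, replicate 3). The split with 727 genes held 2 of the 3 normal libraries in its small group, and that with 107 parted as many donor pairs as the real one and also held 2. Only 1 or 2 other splits per class parted as many pairs, with otherwise at most 1 gene, and none did in endothelial-like, epithelial-like and all cells, so there the real split was set only against splits of other pairing (donor block 6, 0 and 1316). In naive or central memory T-like, B-like, germinal center B-like and memory B-like cells, where the real split called 0 genes, the comparison says nothing, since all 80 must call as many. The highest other counts there were 425, 20, 338 and 122. Each of these splits held 1 normal library in its small group, and a structure of the samples other than tissue, which could give such counts, was not tested.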
